A study of Mus musculus with 12 samples.

How the data were processed

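RNA sequencing of mouse embryonic fibroblasts was analysed in 12 samples, 4 kept in control medium, 4 treated with apigenin and 4 treated with chrysin, each flavone at 50 µM for 24 h. Whether the control medium held the solvent of the flavones is not given in the sources used here. Per the labels' protocols, libraries were made with a stranded mRNA kit. Per the submitters' processing notes, cutadapt, FastQC, STAR, HTSeq and DESeq2 were used with the mouse genome build mm9. Their versions, settings and gene annotation are not given in the sources used here. Nor is the strand setting of the counting, so overlapping and antisense genes are uncertain. How reads shared between copies of a gene were counted is not given either, so levels of genes with near-identical copies, such as Ftl1 and Hmgb2, are uncertain.

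The deposited table held 1 value per gene and sample, on a log2 scale per the labels and the series' design text. Each value was log2 of a normalized read count plus 1, as shown by the values themselves. After that step was undone, the normalized counts of each library fell on whole multiples of one step. Among values under 500 reads, 99.966% to 100.0% lay within 0.05 reads of a whole number, over the 12 libraries. Read totals per library were recovered from these steps, while 5 genes (Areg, Efna1, Krt83, Lipo1 and Ptpra) were not whole in at least 1 library. The authors also deposited a mean log2 value per group. Their 2 deposited ratio columns were the quotient of a treated and an untreated mean log2 value, not a fold change, and 8080 cells of each held no number. In the authors' deposited table, 27 gene names had been turned into calendar dates, and all 27 were restored through the gene ID and the RefSeq gene table of assembly GRCm38.p6, which was used for names only. Of 24458 genes, 24350 had a gene ID also in that table.

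Groups came from the sample titles. Genes with a mean normalized count of at least 10 over all samples were tested, which kept 12198 genes and left out 12260. The deposited log2 values were fitted with limma 3.58.1 in R 4.3.3, with one mean per group over all 12 samples and moderated variances with a trend and robust estimation. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested in each comparison, and a gene was called at an adjusted p under 0.05. Every adjusted p of a gene given here comes from limma. A fold change on this scale understates the change of genes with few reads. Errors are standard errors of the log2 fold change unless SD is named. Nothing in the labels says whether the 4 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

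Before the data were examined, 39 gene lists were fixed, some sharing genes, of which 38 had at least 3 measured genes. They were tested with camera in limma with a preset correlation between genes of 0.01, again with an estimated correlation, and with adjustment over the 38 lists. The mean log2 level of a list in each library was also compared between groups with limma, with 95% confidence intervals. The genes named in the text followed a rule that was also fixed then. For each flavone against untreated it took the 8 largest rises and the 8 largest falls among called genes whose 4 treated values all lay on one side of the 4 untreated values and whose mean was at or above the median of the genes tested, and for apigenin against chrysin the 6 largest of each. It added up to 4 members with the smallest p from each list described, and Cyp1a1, Cyp1b1, Cdkn1a, Hmox1, Ccnb1, Col1a1 and Il6 whatever their values. Predicted genes, pseudogenes, and Y-linked and X-inactivation genes were skipped. Genes named outside the rule are said to be so.

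Both flavones shared the 4 untreated libraries. Their covariance and overlap were therefore set beside 50 simulations of unchanged groups and beside 6 splits of the untreated libraries, 2 for each flavone. The test was checked on simulated data for apigenin against untreated, over 12198 genes with 40 genes changed at each size. It recovered 30% of genes raised by 0.5 on the log2 scale, 77.5% of those raised by 1 and 100% of those raised by 2. It recovered 20% of genes lowered by 0.5 and 67.5% of those lowered by 1, and 7 unchanged genes (5.6% of its calls) were called. Far fewer genes were changed in the simulation than were called in the data (46.2% to 53% of those tested). The adjustment depends on that share, so these recovery rates do not carry over to the real comparisons. Gene coordinates, lengths and GC contents came from GENCODE vM1 on the NCBIM37 assembly, which is mm9.

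Alternatives fixed beforehand were a replicate block, quantile normalization, centring on the median, no filter and a stricter one (mean of at least 50), pseudocounts of 0.25 and 4, limma without trend and robust estimation, array weights, the 8 samples of the 2 groups alone, stricter thresholds and leaving out each library. Added after seeing the data were limma-voom on the recovered reads, fits with apigenin replicates 2 and 4 only or 1 and 3 only, and a GC correction of each library. Cyp1a1, Cyp1a2 and Il6 fell below the filter and were not tested. Some results for single genes are not reported here.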

Results

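The effects of 2 plant flavones on the transcriptome of mouse embryonic fibroblasts, connective tissue cells grown from embryos, were measured by RNA sequencing. Apigenin carries a hydroxyl group on its B ring that chrysin lacks. Cells were left untreated or treated with apigenin or chrysin at 50 µM for 24 h, with 4 libraries per group. Whether the control medium held the solvent of the flavones is not given in the sources used here, so changes against untreated cannot be separated from an effect of solvent. Recovered totals ranged from 4298640 to 15512635 reads per library. Within the chrysin group, replicate 1 held 12957317 reads and the others 4298640 to 5679355. Levels are log2 of the normalized count plus 1. The limit that a count of 0 allows, 3 reads, corresponded to a normalized count of 1.44 in the deepest and 6.24 in the shallowest library, and covers counting error only.

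The first principal component (43.8% of the variance) placed the untreated libraries at -61 to -55.2 and the chrysin libraries at 35.2 to 43.2. The apigenin libraries divided, with replicates 1 and 3 at -4.8 and -7.2 and replicates 2 and 4 at 38.7 and 42.3. On the second component (28.7%), apigenin lay at -51 to -40.5, and chrysin at 22.7 to 46.2.

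**Figure D1:**
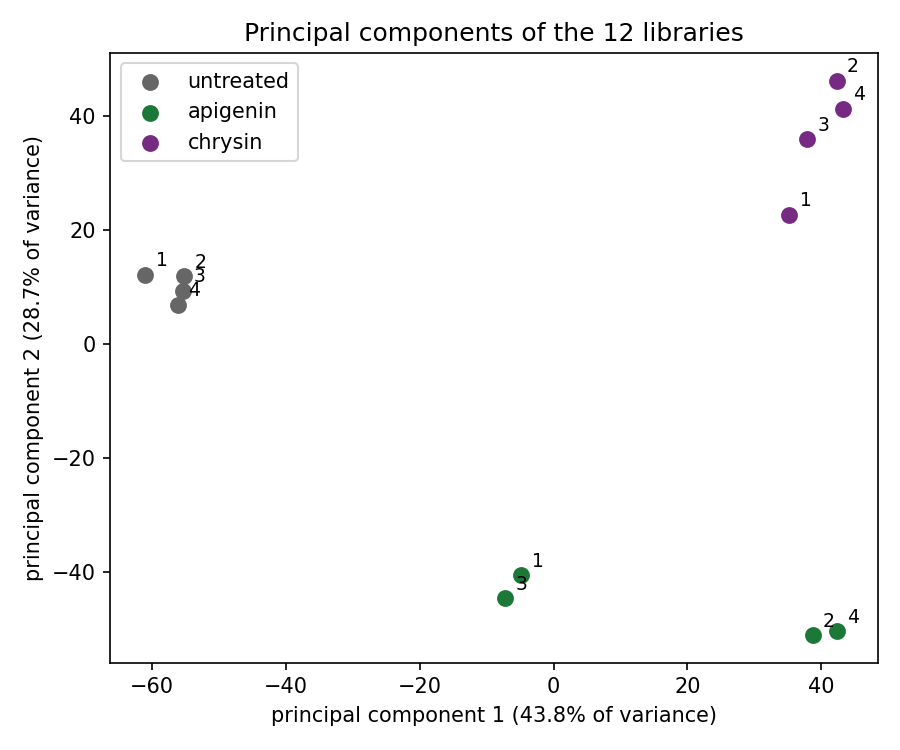
Scores of the 12 libraries on the first and second principal components of the tested genes, with the share of variance on each axis; points are libraries, numbered by replicate and coloured by group. Apigenin replicates 1 and 3 sit at -4.8 and -7.2 on the first component, apart from replicates 2 and 4 at 38.7 and 42.3.

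The first comparison asked what apigenin changed. With apigenin, lists of antioxidant genes were called higher, and lists of cholesterol synthesis, extracellular matrix and contractile genes lower, and the metallothionein genes Mt1 and Mt2 rose. The matrix and contractile calls held with an estimated correlation between genes, and the antioxidant and cholesterol calls did not (adjusted p = 0.117 and adjusted p = 0.222 with an estimated correlation). Hmox1, which encodes heme oxygenase, rose 11.6-fold (log2 3.54 ± 0.08, adjusted p = 3.35e-15, n = 4 per group). Thbs1, the matrix glycoprotein thrombospondin, fell to a level 10.8-fold lower (log2 -3.43 ± 0.1, adjusted p = 2.45e-14). Of 12198 genes tested, 2807 rose and 2824 fell, and 738 and 1062 of these changed by at least 1 on the log2 scale. All 4 treated values lay on one side of all 4 untreated values in 45.1% of genes, where chance gives 2.86%.

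Among the largest rises were Slc7a11, the cystine transporter (3.95 ± 0.11), Srxn1, which repairs oxidised peroxiredoxins (3.34 ± 0.09), and the metallothioneins Mt2 (3.44 ± 0.12) and Mt1 (2.76 ± 0.09). Itgb3, an integrin subunit (2.77 ± 0.31), Gadd45a, a growth arrest gene (2.56 ± 0.23), and Slc43a2, an amino acid transporter (2.5 ± 0.44), completed the 8. The largest falls included the proteoglycan Aspn (-4.1 ± 0.26), the G protein regulator Rgs4 (-3.97 ± 0.39), the imprinted gene Mest (-3.79 ± 0.33) and the elastic fibre genes Fbn2 (-3.6 ± 0.41) and Eln (-3.52 ± 0.14). The cytoskeletal adaptor Sorbs2 (-3.36 ± 0.17) and Cemip, which takes part in hyaluronan breakdown (-3.34 ± 0.31), also fell.

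Of 24 measured NRF2 antioxidant targets, 19 rose, 1 fell and 4 were not called (20 and 1 adjusted over the list alone), with Gclc, of glutathione synthesis, at 2.42 ± 0.09. The list was called (camera, adjusted p = 1.29e-12; adjusted p = 0.117 with an estimated correlation). All 25 cholesterol synthesis genes fell, over all genes and adjusted over the list alone, among them Cyp51 (-1.66 ± 0.13) and Lss (-2.58 ± 0.2). The list median was -1.62 (adjusted p = 2.56e-15; adjusted p = 0.222 with an estimated correlation). Of 16 fatty acid synthesis genes 13 fell and 3 were not called (13 adjusted over the list alone), including Acly (-0.77 ± 0.09) and Elovl6 (-1.83 ± 0.23), with adjusted p = 8.85e-05 (adjusted p = 0.27 with an estimated correlation). The mean cholesterol list level was 8.28 and 8.38 in apigenin replicates 1 and 3, 7.6 and 7.59 in replicates 2 and 4, and 9.55 to 9.96 in untreated libraries. The fatty acid list stood at 9.41 and 9.39 against 8.89 and 8.89, with 9.85 to 9.95 untreated. The NRF2 list stood at 11.25 and 11.29 against 10.85 and 10.81 in the same pairs of apigenin libraries, and at 9.61 to 9.67 in untreated libraries.

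Extracellular matrix genes fell in 35 of 43 members and rose in 2, with the same counts adjusted over the list alone. Col11a1 (-3.29 ± 0.08) and Col8a1 (-2.31 ± 0.08), collagens, had among the smallest p. This list and the contractile list were called under both correlations (matrix adjusted p = 5.85e-14, and adjusted p = 0.0333 with an estimated correlation). Of 26 contractile and SRF target genes, 20 fell, 1 rose and 5 were not called (20 and 1 adjusted over the list alone), with adjusted p = 3.27e-09 (adjusted p = 0.0333 with an estimated correlation). Examples were the LIM protein Fhl2 (-2.62 ± 0.17), vinculin (Vcl, -1.22 ± 0.08) and the actin crosslinker Actn1 (-1.01 ± 0.07). Among YAP and TGF-beta targets 15 of 24 fell and 4 rose (15 and 5 adjusted over the list alone), with Cyr61 at -2.55 ± 0.14, Ctgf at -2.53 ± 0.18 and the growth factors Tgfb2 at -1.52 ± 0.11 and Tgfb1 at 1.48 ± 0.12 (adjusted p = 0.013; adjusted p = 0.0954 with an estimated correlation). Fibroblast markers fell in 11 of 13 members and rose in 1, the same adjusted over the list alone (adjusted p = 7.03e-05; adjusted p = 0.156 with an estimated correlation), including Col1a1 (-1.15 ± 0.1), Col1a2 (-1.33 ± 0.09) and Lum (-3.21 ± 0.28). The mean fibroblast marker level was 10.49 and 10.5 in apigenin replicates 1 and 3, 9.99 and 9.95 in replicates 2 and 4, and 11.29 to 11.4 untreated. The fall of Vim, also in that list (-0.65 ± 0.07), turned to 0.226 (adjusted p = 0.121) after quantile normalization. Of 49 measured markers of other cell types 8 rose and 19 fell, and 5 of 8 pericyte and smooth muscle markers fell, including Lmod1 (-2.5 ± 0.22) and Myh11 (-1.23 ± 0.18). That last call (camera, adjusted p = 0.0428, the same 5 adjusted over the list alone, and adjusted p = 0.418 with an estimated correlation) ended when apigenin replicate 1, apigenin replicate 3, untreated replicate 4 or chrysin replicate 3 was left out (adjusted p = 0.0967, 0.0952, 0.0597 and 0.0505). It also ended with limma-voom, the 8 samples alone, array weights and apigenin replicates 2 and 4 only (camera, adjusted p = 0.0539, 0.0733, 0.113 and 0.231). The lowest over the alternatives was 8.92e-05. Lmod1 and Myh11 are also in the contractile list, and Col1a1, Col1a2 and Lum in the matrix list, so these calls are not independent.

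Interferon response genes fell in 18 of 34 members and rose in 3 (20 and 4 adjusted over the list alone), with the signalling genes Stat2 at -1.33 ± 0.15 and Irf9 at -1.23 ± 0.14 (adjusted p = 0.00791; adjusted p = 0.0954 with an estimated correlation). Lysosome and autophagy genes rose in 19 of 41 and fell in 1, the same adjusted over the list alone, with the autophagy receptor Sqstm1 at 1.66 ± 0.1 and the galactosidase Gla at 1.46 ± 0.12 (adjusted p = 0.000586; adjusted p = 0.27 with an estimated correlation). Of 32 immediate early genes 18 rose and 5 fell (19 and 5 adjusted over the list alone; adjusted p = 0.013; adjusted p = 0.601 with an estimated correlation). The members with the smallest p included Nr4a2, a nuclear receptor, which rose (1.43 ± 0.13), and Spry1, a feedback inhibitor of receptor tyrosine kinases, and Klf4, which fell (-3.11 ± 0.19 and -1.18 ± 0.1). The mean list level was 7.72 and 7.7 in apigenin replicates 1 and 3, 8.52 and 8.54 in replicates 2 and 4, and 7.38 to 7.71 untreated. This call ended with apigenin replicates 1 and 3 only, where the median fell from 0.7 to 0.19 (adjusted p = 0.186; lowest over the alternatives 2.93e-05), and after GC correction, where the median stayed at 0.7 (adjusted p = 0.0524).

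The 40 mitosis genes did not change as a list (2 rose and 1 fell, and 1 and 0 adjusted over the list alone; adjusted p = 0.915), while their mean level divided the apigenin libraries. It was 7.15 and 7.16 in replicates 1 and 3, 5.73 and 5.65 in replicates 2 and 4, and 6.35 to 6.69 in untreated libraries. Ccnb1, the mitotic cyclin, stood at 7.71, 5.69, 7.33 and 5.77 in apigenin replicates 1 to 4 (0.37 ± 0.38, adjusted p = 0.442). With apigenin replicates 2 and 4 only, 26 members fell and the list was called (adjusted p = 0.000224), and with replicates 1 and 3 only, 23 rose (adjusted p = 1.26e-07). These library choices were made after the division was seen. Of 26 p53 targets 10 rose and 4 fell (10 and 5 adjusted over the list alone; adjusted p = 0.101 by camera), while their mean level differed by 0.3 (95% CI 0.16 to 0.44, adjusted p = 0.0011). That level was 9.46 and 9.55 in apigenin replicates 1 and 3, 9.74 and 9.7 in replicates 2 and 4, and 9.28 to 9.34 untreated. The ubiquitin ligase Mdm2 rose (1.24 ± 0.12), and the cell cycle inhibitor Cdkn1a stood at 0.11 ± 0.07 (adjusted p = 0.227). Aryl hydrocarbon receptor targets were not called (2 rose and 1 fell of 8, the same adjusted over the list alone; median -0.12, although camera pointed up, adjusted p = 0.915). Their mean level divided as well, at 7.58 and 7.35 in apigenin replicates 1 and 3 and 6.58 and 6.51 in replicates 2 and 4, against 6.72 to 7.27 untreated. Nqo1, a quinone reductase, rose (1.63 ± 0.34), Ahrr, the repressor of the receptor, fell (-1.98 ± 0.44). Cyp1b1, which oxidises xenobiotics, stood at 12.04, 10.39, 11.87 and 10.43 in replicates 1 to 4 against 11.68 to 11.81 untreated (-0.56 ± 0.34, adjusted p = 0.207). Cyp1a1 had 0 to 3 reads per library and Il6 0 to 7, so neither could be compared at this depth.

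**Figure D2:**
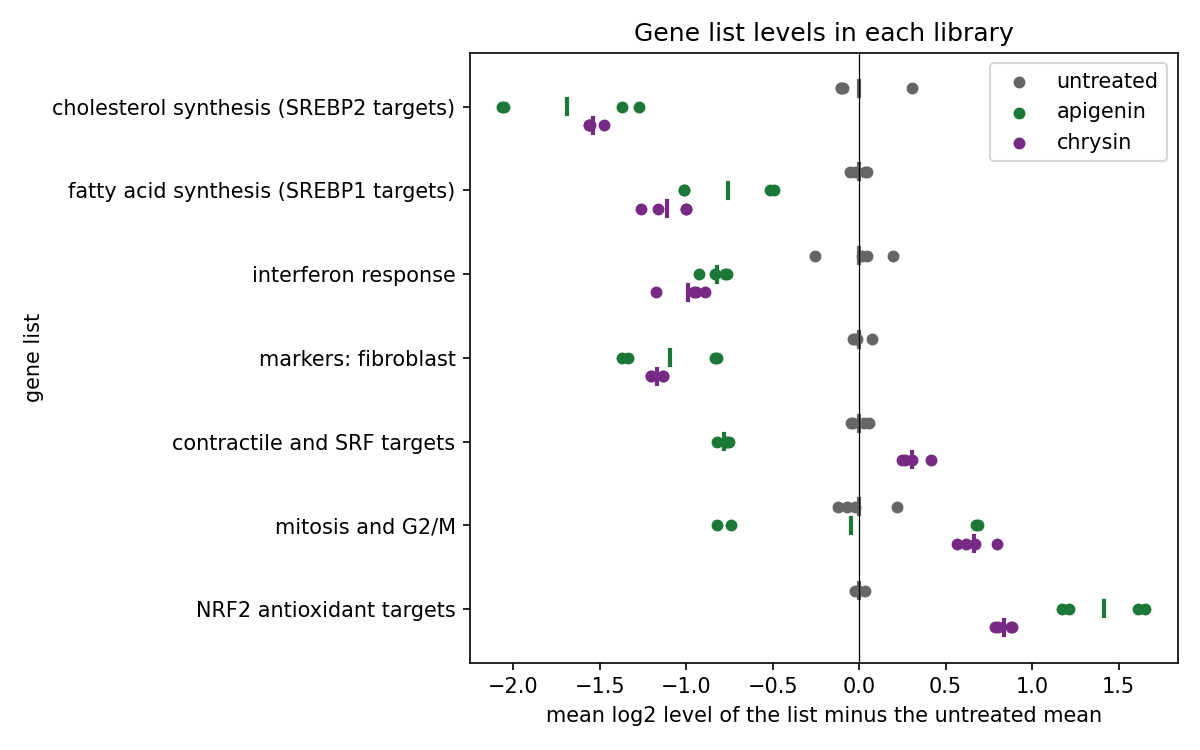
Mean log2 level of 7 gene lists in each library minus the mean of the untreated libraries; points are libraries, short bars are group means. The 4 apigenin libraries lie below and the 4 chrysin libraries above all untreated libraries for the contractile list, and the apigenin libraries divide on the mitosis list at 7.15 and 7.16 against 5.73 and 5.65 in level.

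The second comparison asked what chrysin changed. With chrysin, lists of clock, heat shock, ribosome biogenesis, antioxidant and inflammatory genes were called higher, and lists of sterol synthesis, matrix and interferon response genes lower, with a preset correlation between genes. Of 38 lists 0 were called by camera with an estimated correlation (smallest adjusted p = 0.164), and the inflammatory call also ended under some alternatives. Each list had 1 estimate, taken from all 12 libraries. For the inflammatory and interferon lists it was 0.004 and 0.007, below the preset 0.01, so a higher correlation did not end those calls. Ptgs2, the inducible cyclooxygenase, rose 11.5-fold (log2 3.52 ± 0.16, adjusted p = 2.91e-10, n = 4 per group). Neat1, a nuclear long noncoding RNA, was 12.6-fold lower (log2 -3.66 ± 0.38, adjusted p = 1.65e-05). Of 12198 genes, 3208 rose and 3251 fell, and 948 and 1370 of these changed by at least 1 on the log2 scale. Treated and untreated values did not overlap in 51.4% of genes, where chance gives 2.86%.

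The other large rises were Slc7a11 (3.52 ± 0.11), the chromatin protein Hmgb2 (3.2 ± 0.36), the AP-1 subunit Fosl1 (3.01 ± 0.21), Rad54l2 (2.75 ± 0.19), the signal transducer Smad1 (2.67 ± 0.33), Pcf11, a factor in transcript cleavage and termination (2.6 ± 0.12), and the protease Plau (2.59 ± 0.45). Large falls were seen in Aspn (-3.61 ± 0.26), the proteoglycan Dcn (-3.59 ± 0.46), the growth arrest genes Gas2 (-3.53 ± 0.35) and Gas1 (-3.1 ± 0.28), Cyr61 (-3.28 ± 0.14), the noncoding RNA Dnm3os (-3.24 ± 0.39) and the collagen Col3a1 (-2.98 ± 0.32).

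Cholesterol synthesis genes fell in 24 of 25 members, over all genes and adjusted over the list alone, with Dhcr7 at -2.18 ± 0.13 (adjusted p = 2.58e-11; adjusted p = 0.242 with an estimated correlation). The remaining member was not called. Of 16 fatty acid synthesis genes 11 fell (12 adjusted over the list alone), Acss2 by -2.94 ± 0.3 (adjusted p = 1.56e-05; adjusted p = 0.231 with an estimated correlation). Matrix genes fell in 30 of 43 and rose in 6, the same adjusted over the list alone, including Col11a1 (-2.25 ± 0.08), Eln (-2.82 ± 0.14) and Postn (-1.37 ± 0.09), with adjusted p = 1.11e-06 (adjusted p = 0.17 with an estimated correlation). Fibroblast markers fell in 9 of 13 (10 adjusted over the list alone; adjusted p = 0.00023; adjusted p = 0.202 with an estimated correlation), with Col1a1 at -1.27 ± 0.1 and Col1a2 at -1.39 ± 0.09. Of 49 markers of other cell types 10 rose and 14 fell.

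NRF2 targets rose in 14 of 24 and fell in 3 (15 and 3 adjusted over the list alone; adjusted p = 2.57e-05; adjusted p = 0.265 with an estimated correlation), with Hmox1 at 2.47 ± 0.08 and Srxn1 at 2.02 ± 0.09. Heat shock genes rose in 16 of 24 with none lower, the same adjusted over the list alone, among them Hspd1 (1.09 ± 0.08), Hsph1 (1.06 ± 0.09) and the co-chaperone Bag3 (0.96 ± 0.09), with adjusted p = 1.27e-05 (adjusted p = 0.231 with an estimated correlation). Ribosome biogenesis and MYC target genes rose in 19 of 28 and fell in 1 (20 and 1 adjusted over the list alone; adjusted p = 1.56e-05; adjusted p = 0.164 with an estimated correlation). Gnl3, a nucleolar GTPase (1.55 ± 0.1), and Ubtf, a factor of ribosomal RNA transcription (0.93 ± 0.08), rose, and the 1 that fell was Myc itself (-1.37 ± 0.14).

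Circadian clock genes rose in 11 of 18 and fell in 2, the same adjusted over the list alone, with the repressors Nr1d1 at 2.36 ± 0.13, Per1 at 2.1 ± 0.13 and Bhlhe40 at 1.47 ± 0.11 (adjusted p = 0.000315; adjusted p = 0.17 with an estimated correlation). Of 24 NF-kB and inflammatory genes 12 rose and 5 fell (12 and 6 adjusted over the list alone), including the inhibitor Nfkbia (1.78 ± 0.14) and the cytokines Csf1 (1.61 ± 0.13) and Lif (3.01 ± 0.29). That list was called at adjusted p = 0.0268 (adjusted p = 0.17 with an estimated correlation), and not in the fit with the 8 samples alone (median 0.68 in both, adjusted p = 0.0566) or after GC correction (median 0.72, adjusted p = 0.0545; range over all alternatives 0.0183 to 0.0666). Interferon response genes fell in 20 of 34 and rose in 3, the same adjusted over the list alone (adjusted p = 0.00156; adjusted p = 0.164 with an estimated correlation). The GTPase Irgm1 (-2.04 ± 0.14) and Stat2 (-1.61 ± 0.15) fell, and the transcription factor Irf1 rose (1.51 ± 0.14).

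Of 26 contractile and SRF target genes 15 rose and 5 fell, the same adjusted over the list alone, with smooth muscle actin (Acta2) at 0.69 ± 0.07 and Srf at 0.87 ± 0.1 (adjusted p = 0.0192; adjusted p = 0.242 with an estimated correlation). After quantile normalization this list was not called (adjusted p = 0.0551; lowest over the alternatives 0.00671). DNA replication genes rose in 16 of 39 with none lower, the same adjusted over the list alone, including Rrm2 (1.35 ± 0.1), Mcm2 (1.78 ± 0.19) and Cdt1 (2.18 ± 0.22), with adjusted p = 0.00245 (adjusted p = 0.202 with an estimated correlation). Mitosis genes rose in 11 of 40 with none lower (9 adjusted over the list alone), including Spc25 (1.82 ± 0.2), Incenp (0.72 ± 0.15) and Aurka (0.98 ± 0.24), with adjusted p = 0.00281 (adjusted p = 0.726 with an estimated correlation). Ccnb1 stood at 0.78 ± 0.38 (adjusted p = 0.0966). Cdkn1a fell (-0.44 ± 0.07, adjusted p = 9.67e-05). Cyp1b1 fell as well (-1.73 ± 0.34, adjusted p = 0.00152), although its list was not called (1 rose and 5 fell of 8, the same adjusted over the list alone; adjusted p = 0.43).

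**Figure D3:**
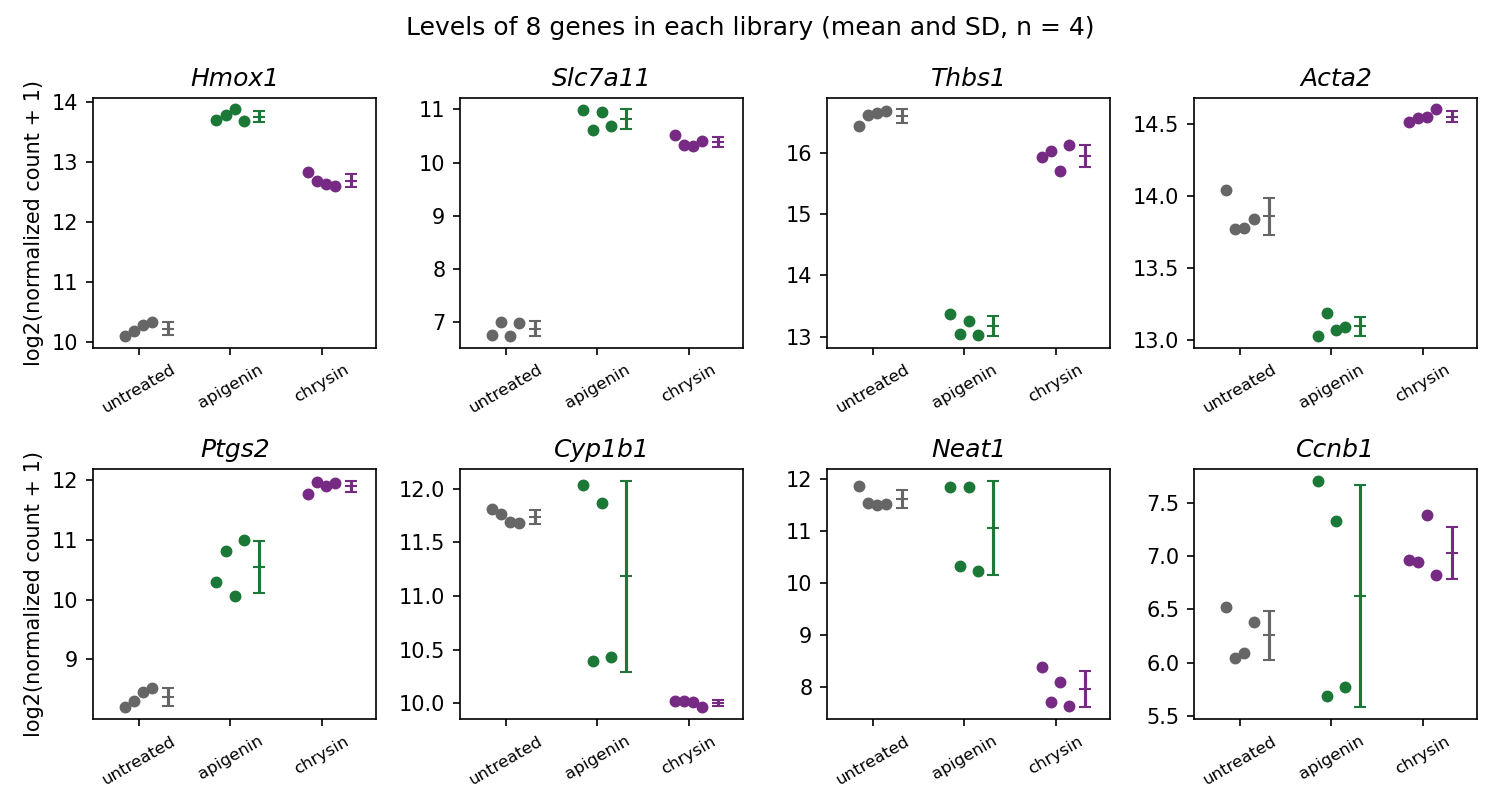
Levels of 8 genes in each library as log2 of the normalized count plus 1, on axes that do not start at 0; points are libraries, bars are the mean and SD of 4 libraries per group. Cyp1b1 stood at 12.04, 10.39, 11.87 and 10.43 in the apigenin libraries.

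The third comparison set the flavones against each other at the same dose and time, and so tested the difference between their responses. Contractile genes were lower in apigenin in 25 of 26 members with none higher, the same adjusted over the list alone (median -1.06, adjusted p = 7.06e-14; adjusted p = 0.0098 with an estimated correlation). The mean of that list differed by -1.09 (95% CI -1.2 to -0.98), with Tpm1 at -1.66 ± 0.07, Vcl at -1.68 ± 0.08, Fhl1 at -2.34 ± 0.11 and Acta2 at -1.45 ± 0.07. NF-kB and inflammatory genes were lower in apigenin in 14 of 24 and higher in 1, the same adjusted over the list alone (adjusted p = 0.000162; adjusted p = 0.0265 with an estimated correlation), including the NF-kB inhibitor Tnfaip3 (-4.03 ± 0.32), Birc3 (-2.01 ± 0.21) and Il1rn, the interleukin receptor antagonist (-2.71 ± 0.19). In all, 3011 genes were higher and 3179 lower in apigenin than in chrysin, and 1057 and 838 of these differed by at least 1.

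Among genes at or above the median level, those with the largest differences were Neat1 (3.11 ± 0.38), Mmp11, a matrix protease (2.57 ± 0.13), Dnm3os (2.41 ± 0.39), Itgb3 (2.27 ± 0.31), the transcription factor Sox4 (2.18 ± 0.16) and Tmem140 (2.14 ± 0.25), all higher in apigenin. Lower in apigenin were Sorbs2 (-2.98 ± 0.17), the choline transporter Slc5a7 (-2.9 ± 0.79), Thbs1 (-2.78 ± 0.1), Ctgf (-2.78 ± 0.18) and Pcf11 (-2.76 ± 0.12). Pcf11 rose in chrysin and stood at -0.16 ± 0.12 in apigenin (adjusted p = 0.313).

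NRF2 targets were higher in apigenin in 15 of 24 and lower in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.000162; adjusted p = 0.393 with an estimated correlation). Hmox1 was higher by 1.07 ± 0.08, Srxn1 by 1.32 ± 0.09 and the ferritin light chain Ftl1 by 1.49 ± 0.13. Lysosome genes were higher in 20 of 41 and lower in 5, the same adjusted over the list alone, with Psap at 0.82 ± 0.07 and Grn at 0.86 ± 0.08 (adjusted p = 0.00358; adjusted p = 0.393 with an estimated correlation). FOXO-responsive genes were higher in 13 of 21 and lower in 2 (14 and 2 adjusted over the list alone; adjusted p = 0.00358; adjusted p = 0.393 with an estimated correlation). In that list Pik3ip1, a negative regulator of PI3 kinase, and the mitophagy kinase Pink1 differed by 2.01 ± 0.12 and 1.35 ± 0.11. Ribosome biogenesis genes were lower in apigenin in 18 of 28 and higher in 2 (19 and 2 adjusted over the list alone; adjusted p = 0.000162; adjusted p = 0.169 with an estimated correlation), with Gnl3 at -1.44 ± 0.1 and Nop58 at -1.21 ± 0.1. Clock genes were lower in 10 of 18 and higher in 1, the same adjusted over the list alone, with Per1 at -1.96 ± 0.13 and Ciart at -3.26 ± 0.26 (adjusted p = 0.00433; adjusted p = 0.393 with an estimated correlation). Heat shock genes were lower in 16 of 24 and higher in 2 (17 and 3 adjusted over the list alone), including Hspa4 (-1.1 ± 0.1) and Hspa9 (-0.98 ± 0.09), at adjusted p = 0.00208 (adjusted p = 0.425 with an estimated correlation). The call ended after quantile normalization (adjusted p = 0.0547; lowest over the alternatives 0.000213).

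Matrix genes were lower in apigenin in 22 of 43 and higher in 5 (22 and 6 adjusted over the list alone; adjusted p = 0.00823; adjusted p = 0.393 with an estimated correlation). That call ended after quantile normalization (adjusted p = 0.566) and with apigenin replicates 1 and 3 only (adjusted p = 0.244), with 7.5e-05 the lowest over the alternatives. Mitosis genes were lower in 14 of 40 (4 adjusted over the list alone; adjusted p = 0.00609; adjusted p = 0.725 with an estimated correlation). That call was lost without apigenin replicate 4 (adjusted p = 0.0576) and with replicates 1 and 3 only (adjusted p = 0.98; lowest over the alternatives 5.44e-11). Pericyte and smooth muscle markers were lower in 5 of 8, the same adjusted over the list alone (adjusted p = 0.0192; adjusted p = 0.393 with an estimated correlation). This call ended with apigenin replicates 2 and 4 only (adjusted p = 0.0737; lowest over the alternatives 0.000546).

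The groups that were lower with both flavones were also compared by their mean level, which for matrix genes differed by -0.35 (95% CI -0.51 to -0.19, adjusted p = 0.00145). The mean cholesterol synthesis level differed by -0.15 (95% CI -0.54 to 0.23) and the list was not called (3 higher and 8 lower of 25, the same adjusted over the list alone; adjusted p = 0.454). Single genes differed, Cyp51 by -0.91 and Dhcr7 by 0.9 (adjusted p = 3.05e-05 and 2.45e-05). With apigenin replicates 2 and 4 only the list was lower in apigenin (adjusted p = 0.000971; highest over the alternatives 0.783). Interferon response genes differed by 0.17 (95% CI -0.04 to 0.37) and fibroblast markers by 0.08 (95% CI -0.18 to 0.33). The fibroblast list median was -0.09 and camera pointed down (2 higher and 3 lower of 13, the same adjusted over the list alone; adjusted p = 0.923). Fatty acid synthesis differed by 0.35 (95% CI 0.08 to 0.62), with adjusted p = 0.0291 for the list level and adjusted p = 0.139 by camera. The camera call appeared without apigenin replicate 2 (adjusted p = 0.0465), without apigenin replicate 4 (adjusted p = 0.0448) and with replicates 1 and 3 only (adjusted p = 0.00134; highest over the alternatives 0.751). Col1a1 differed by 0.12 (95% CI -0.09 to 0.34, adjusted p = 0.335) and Ccnb1 by -0.4 ± 0.38 (adjusted p = 0.389), whereas Cdkn1a and Cyp1b1 were higher in apigenin (0.55 ± 0.07 and 1.18 ± 0.34). For Cyp1b1 the apigenin libraries divided, with replicates 1 and 3 higher than replicates 2 and 4. Across the 10998 genes with a known GC content, the difference between the flavones followed GC content with a rank correlation of 0.321, across genes that are not independent replicates.

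The responses to the flavones were compared across genes. In both, 1475 genes rose and 1494 fell in common, 2969 in all, against 738 and 753 for independent lists, and 458 went opposite ways against 1491. Unchanged groups sharing the untreated libraries gave 0 genes in 50 simulations. Such groups hold hardly any called genes, so that 0 was fixed in advance and does not show what shared controls add. With the untreated libraries split between the flavones the overlap averaged 1756 (1727 to 1793). Each flavone then had fewer untreated libraries, so the lower count mixes less sharing with less power. The log2 fold changes had a covariance of 0.472, against 0.038 simulated, a difference of 0.435, and 0.449 with split controls. Pearson's r across genes was 0.61, against 0.5 simulated and 0.56 with split controls, across genes that are not independent replicates. Matrix genes lower in both numbered 28, of which 24 were called lower in both after quantile normalization and 28 after centring on the median.

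**Figure D4:**
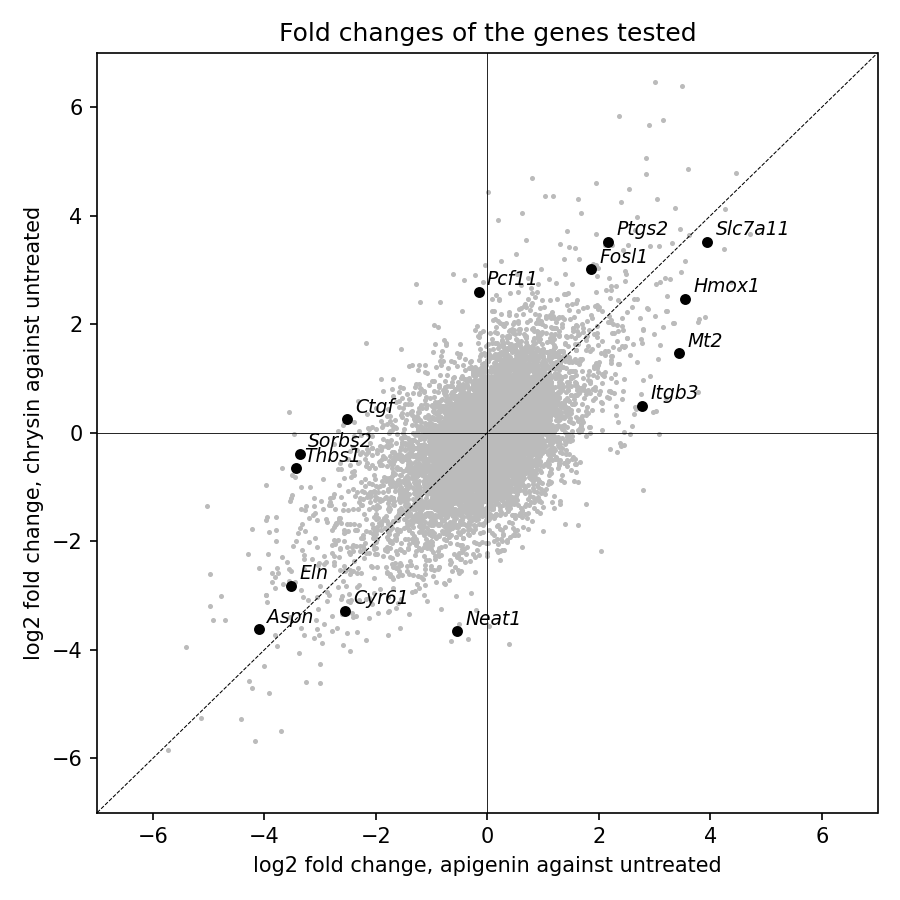
Log2 fold changes of the 12198 genes tested, apigenin against untreated on the horizontal and chrysin against untreated on the vertical axis; black points are named genes and the dashed line marks equal change. Slc7a11 lies high on both axes (3.95 and 3.52), while Neat1 and Pcf11 lie far from the line.

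On the mm9 build, Hmox1 spans chromosome 8 from 77617490 to 77624495 and Slc7a11 chromosome 3 from 50168858 to 50247535. Thbs1 lies on chromosome 2 from 117937612 to 117952869, Ptgs2 on chromosome 1 from 151947254 to 151955140, and Cyp1b1 on chromosome 17 from 80106234 to 80114401, all protein-coding. Neat1, annotated as a processed transcript, lies on chromosome 19 from 5824708 to 5845478. The reads of each were counted over whole genes, so no exon or UTR is singled out.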

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

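The tests chosen only after the result was seen were those of a swap with chrysin libraries, of GC bias of single libraries and of a lower share of fibroblasts, the matrix list under other scalings, the GC correction, and the fits with apigenin replicates 1 and 3 or 2 and 4 only.

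Library levels (log2) and read totals were searched for 1 library far from the other 3 of its group, by Dixon's test. The search covered the read totals and the genes and lists picked for the text, a choice made after the values were seen. Of 381 groups 20 (5.2%) held one, and chance gives about 1 in 20. The flags were not spread evenly, as untreated replicate 1 held more of them than any other library. Its total was 4865170 reads, against 9664688 to 12871962 in the other untreated libraries. Untreated replicate 1 stood above the others for Acly at 12.19, Dhcr7 at 9.79, Eln at 11.42, Lss at 10.6, Neat1 at 11.87 and the cholesterol list at 9.96. It stood below them for Gla at 8.51, Il1rn at 8.38, Rad54l2 at 7.98, Slc5a7 at 6.81 and Tmem140 at 6.99. Untreated replicate 3 was lowest for Ahrr at 7.69 and untreated replicate 2 for Bag3 at 10.46. Apigenin replicate 3 was lowest for Ep300 at 10.4, and apigenin replicate 1 for Mt2 at 12.07. Chrysin replicate 2 was lowest for Cdkn1a at 11.98, and chrysin replicate 3 for Tnfaip3 at 6.97. Chrysin replicate 3 was highest for Mt1 at 11.78 and the cholesterol list at 8.18. The total of chrysin replicate 1 was 12.96 M reads, against 4.3 to 5.68 M reads in the other chrysin libraries (M, mega).

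Apigenin replicates 1 and 3 deviated from the apigenin mean together, as did replicates 2 and 4 (Pearson's r across genes 0.45 and 0.55). Sequencing depth alone does not account for this, since after thinning each library to 4212667 reads the correlations were 0.38 and 0.42. A swap with chrysin libraries is argued against by the second component, where the flavones lay 63.2 apart with ranges of 10.5 and 23.5 within them. A weaker form of one response in replicates 1 and 3 falls short as the whole account, although the genes leaned that way. Of the 1800 genes changed by at least 1, 64.9% (95% CI 62.6 to 67.1) lay further from untreated in both replicates 2 and 4, where over 90 was set for it. A share of 12.6% lay further in both replicates 1 and 3, chance gives 16.7% each, and the mitosis list lay on opposite sides of untreated. The interval is taken over genes, which are not independent replicates, and does not cover the spread between libraries. A culture, day or batch difference stays open, as the labels give none to test.

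Chrysin fold changes followed genomic length (rank correlation 0.112) over part of its range, with medians from -0.28 in the shortest to 0.16 in the eighth of 10 groups of genes by length but -0.15 in the longest, and the flavones differed along GC content (0.321), over 10998 genes. Few reads in the shallow chrysin libraries do not account for the first, which was 0.111 among genes with at least 100 reads on average. Adjusted for GC content it was 0.058, and adjusted for mRNA length 0.065, so that neither of these can be told apart from length, the values lying between the bounds set for each. GC bias of single libraries stays open too, since the rank correlations of the libraries with GC content were parted by only 0.063 between the flavones, with ranges of 0.156 and 0.186 within them. After GC correction 5310, 5861 and 5327 genes were called, against 5140, 5917 and 5671 of the same genes without it.

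Fibroblast markers and matrix genes were lower in both flavones. A lower share of fibroblasts, with the other cell types in unchanged proportions, would raise the markers of those types alike. Marker lists that moved apart speak against that form as the whole cause, if the markers came from those cells, which bulk RNA cannot show. They cannot decide about a lower share with a gain of only 1 other cell type. With apigenin the macrophage list stood at 0.32 (95% CI -0.14 to 0.78) and the neural list at -1.1 (95% CI -1.37 to -0.83), a gap of 0.69 between the intervals, and with chrysin the skeletal muscle list, of 3 measured genes, stood at 0.59 (95% CI 0.12 to 1.07) and the endothelial list at -0.92 (95% CI -1.22 to -0.61), a gap of 0.73. These were the highest and lowest lists, picked after the values were seen, and the intervals make no allowance for that. By camera none of them was called (adjusted p = 0.334, 0.107, 0.411 and 0.311, in the order given). The macrophage level in apigenin replicates 2 and 4 (5.34 and 5.3) lay within the untreated range of 5.05 to 5.55. Scaling of the libraries as the whole cause is argued against only by list calls, a criterion added after the values were seen. The matrix list was still lower after quantile normalization (camera, adjusted p = 1.13e-09 with apigenin and 2.23e-08 with chrysin). Of the 28 matrix genes lower in both, 85.7% were still called so (28 of 28 after centring on the median). This missed the bound of 90 set first, so by that bound the question was not decided. A response of the fibroblasts to the flavones stays open, as does a part played by a changed mix of cells or by scaling.

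Other divisions of the libraries were tested against the real one. For genes changed, 1 of 35 divisions, the real one, gave as many in each comparison (5631, 6459 and 6190 genes, highest other 0). That is the smallest share that 35 divisions can give, so chance is unlikely for these counts but not excluded. The other divisions mix the groups, which widens the spread within each side, so a count of 0 there was likely in advance. For lists called, 17, 8 and 10 of 35 gave as many (11, 13 and 12 lists, highest others 16, 17 and 14), which decides nothing about chance. Divisions that keep 3 of the 4 libraries of a group together still hold part of the treatment difference, and gave the 16 and 17 lists, and the 14 came from divisions that kept apigenin replicates 1 and 3 apart from 2 and 4. With 2 libraries of each group on both sides, chrysin and untreated gave 0 to 4 lists, but apigenin and untreated gave 9 to 12 where apigenin replicates 1 and 3 were set against 2 and 4 and 0 to 3 otherwise. The overlap of 2969 genes and the covariance of 0.472 were each reached in 1 of 100 regroupings, the real one (highest others 0 and 0.355). The other regroupings also mix the groups, so an overlap of 0 there was likely in advance and says little about a shared response.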

How the results depend on the processing

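The fits with limma-voom, with apigenin replicates 1 and 3 or 2 and 4 only and with GC correction were chosen after the data were seen. Of 488 named gene results under 28 alternatives, 4530, 4497 and 4380 kept their status as called or not called in the 3 comparisons (apigenin, chrysin, apigenin against chrysin). A further 37, 47 and 40 lost the call and 23, 21 and 3 gained it. Direction was compared only where the main fit or the alternative called the gene, so sign changes of genes called in neither were not counted. Among results called in either fit 4 turned, all after quantile normalization: Vim to 0.226 with apigenin and, for apigenin against chrysin, Vim to 0.179, Atp5b to 0.099 and Rpl4 to 0.01 (log2, the cause was not tested). With an estimated correlation 2, 0 and 2 lists were called. By construction, requiring a change of at least 1 left 1800, 2318 and 1895 genes and an overlap of 864, and a threshold of 0.01 an overlap of 1886. The covariance of the responses (0.472) moved to 0.371 with the stricter filter, 0.395 and 0.52 with pseudocounts of 4 and 0.25, 0.525 with array weights, 0.518 with limma-voom, and 0.622 and 0.322 with apigenin replicates 2 and 4 or 1 and 3 only (the cause was not tested). Leaving out each library gave a covariance of 0.418 to 0.527, 4782 to 5860, 5765 to 6643 and 5438 to 6151 genes, 10 to 13, 13 to 14 and 11 to 14 lists and an overlap of 2471 to 3187. The share of higher among called genes (49.8%, 49.7% and 48.6%) was 53.6%, 50.1% and 50.3% after quantile normalization, 46.6%, 51.7% and 43.4% after centring on the median, and 55.1%, 55.2% and 46.9% after GC correction. Limma-voom called 6239, 6229 and 5946 genes. Same-numbered libraries of different groups did not deviate together (12 pairs, -0.1 to 0.1, with 3 of 12 libraries nearest to their own number), and with the replicate block 5481, 6279 and 6037 genes, 11, 13 and 12 lists and an overlap of 2899 were called. Depth limits weakly expressed genes most, as the 3-read limit differed from 1.44 to 6.24 normalized counts.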

Other observations

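The tests of imprinted and of Y-linked genes, and the fits with apigenin replicates 1 and 3 only, were chosen only after the result was seen.

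Glycolysis and hypoxia genes went both ways. Of 27 measured, 14 rose and 6 fell with chrysin (15 and 6 adjusted over the list alone), and the list was not called (adjusted p = 0.14). Hk2, a hexokinase, rose (1.76 ± 0.16), while Aldoc, an aldolase, and the hypoxia-responsive Ndrg1 fell (-3.31 ± 0.34 and -2.03 ± 0.11). Among 39 DNA and chromatin modifying enzymes 12 rose and 12 fell with chrysin, the same adjusted over the list alone (adjusted p = 0.776). The methyltransferase Ezh2 and the acetyltransferase Ep300 rose (1.2 ± 0.13 and 1.27 ± 0.1).

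Of 11 measured macrophage and leukocyte markers 5 were higher and 1 lower in apigenin than in chrysin, the same adjusted over the list alone, and the list was not called (adjusted p = 0.079), although its mean level differed by 0.73 (adjusted p = 0.00955). The call appeared with the stricter filter (adjusted p = 0.0119), with apigenin replicates 1 and 3 only (adjusted p = 0.0279) and without apigenin replicate 2 or 4 or chrysin replicate 3 or 4 (adjusted p = 0.0495, 0.0448, 0.0468 and 0.0489; highest over the alternatives 0.253). Cd68 and Laptm5, lysosomal membrane proteins, differed by 1.25 ± 0.11 and 1.57 ± 0.2. Cd14, a coreceptor for lipopolysaccharide, stood at 6.07 to 6.72 in apigenin, 3.44 to 4.99 in untreated and 0 to 4.67 in chrysin libraries. Conjugating enzymes and efflux transporters were higher in apigenin in 10 of 18 and lower in 3, the same adjusted over the list alone (adjusted p = 0.0381; adjusted p = 0.393 with an estimated correlation), with the glutathione transferase Mgst1 at 1.48 ± 0.12 and the transporter Abcg2 at -1.3 ± 0.14. That call ended without apigenin replicate 1 or 3 (camera, adjusted p = 0.0638 and 0.0574). It also ended with limma-voom, array weights, no filter and the stricter filter (adjusted p = 0.0509, 0.0582, 0.0591 and 0.0935). With apigenin replicates 2 and 4 only it ended as well (adjusted p = 0.0996), and the lowest over the alternatives was 0.00326. Neural and glial markers were not called with apigenin (1 rose and 3 fell of 9, and 2 and 5 adjusted over the list alone; adjusted p = 0.107 by camera), although their mean level differed by -1.1 (95% CI -1.37 to -0.83, adjusted p = 9.5e-06), and the tubulin Tubb3 and the microtubule protein Map2 fell (-3.68 ± 0.33 and -2.34 ± 0.32).

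One hypothesis was that imprinted growth genes fell as a group, a list drawn up after Mest was seen among the largest falls. Of 20 measured, 16 fell and 1 rose with apigenin, and 12 fell and 2 rose with chrysin, with camera p of 1.86e-06 and 8.92e-05. With an estimated correlation p was 0.102 and 0.168, and the flavones did not differ past the threshold (p = 0.639). The data may thus hold a joint fall of these genes, a hypothesis found and tested on the same libraries.

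Another was that apigenin cultures held a lower share of male cells, since Y-linked genes, outside the rule for named genes and chosen after their values were seen, were lower. Ddx3y and Eif2s3y fell with apigenin (-1.01 ± 0.14 and -0.83 ± 0.22), and Kdm5d and Uty stood at -0.48 ± 0.47 and -0.11 ± 0.37. Kdm5d stood at 7.01 and 6.58 and Uty at 6.79 and 6.68 in apigenin replicates 1 and 3, above all untreated libraries (5.94 to 6.49 and 5.75 to 6.3), and at 4.37 and 4.85 and 5.01 and 5.64 in replicates 2 and 4, below them, so the condition that all apigenin libraries be lower was not met. With chrysin Kdm5d fell (-1.86 ± 0.47, adjusted p = 0.0035) and Ddx3y stood at -0.13 ± 0.14. In replicates 1 and 3 Ddx3y stood at 7.77 and 7.58, below the untreated libraries (8.35 to 8.59), where Kdm5d and Uty stood above them. For these 2 libraries this argues against a lower share of male cells as the whole account. In replicates 2 and 4 each of the Y-linked genes named was below all untreated libraries. Over all 4 apigenin libraries, the largest difference between the fold changes was 2.25 of its standard errors, under the 3 set for excluding a lower share of male cells. That value mixes the 2 pairs of libraries and was not computed for replicates 2 and 4 alone. For replicates 2 and 4 a lower share stays open and cannot be told apart from changes of single genes.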
